A study of Caenorhabditis elegans with 4 samples.

How the data were processed

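The data were 3 lists of EFL-1 binding regions (peaks) from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in first-stage (L1) larvae of Caenorhabditis elegans grown at 26 degrees C. EFL-1 is an E2F-family transcription factor of the worm. The series held 4 samples, namely 2 ChIP libraries and 2 libraries of input DNA, which is crosslinked chromatin set aside before the precipitation. Per the labels' protocols, worms were fixed with formaldehyde, chromatin was sheared by sonication, and the complexes were collected on antibody-coated beads. The labels disagree on the antibody. The series title names a GFP-tagged EFL-1 and the protocol describes an anti-GFP precipitation, whereas the sample names give the N2 strain with "Ab" and a wild-type genotype. Whether EFL-1 itself or a tag was precipitated was therefore left open.

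Each list gave the chromosome, start and end of every peak and 1 measurement, a q-value (a p-value corrected for multiple testing). Per the file headers, positions refer to the WormBase WS220 genome build, and per the source column of the deposited lists the authors called peaks with PeakSeq, whose version is not given in the sources used here. The lists hold no q-value above 0.01. The authors deposited 1 list for each ChIP replicate and 1 combined list. How the combined list was made, the aligner, the read filters and the way input was used in the calling are not given in the sources used here. Comments in the deposited files record that positions were lifted over from another build, which changed the length of 7 combined peaks, 5 peaks of replicate 1 and 5 of replicate 2. No read counts accompany the peaks, so the sequencing depth behind each library is unknown, and a q-value mixes enrichment with depth. The input libraries entered no analysis here except through the authors' peak calling. The combined list was treated as the authors' list for both replicates, with no replicate error of its own.

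Peaks were ranked by −log10 of the deposited q-value, and this number is called peak strength below. Peaks of different lists were matched when they overlapped by at least 1 bp, and the best-scoring partner was kept. The share of overlapping peaks was compared with 1000 random placements of the same peaks within their chromosomes (one-sided permutation test, for which 0.001 is the smallest possible p). Strengths were correlated over pairs of peaks that were each other's best partner, with a 95% interval from 500 bootstrap draws over peaks. The span of a chromosome was taken from position 1 to the last peak end in any of the 3 lists, since no WS220 chromosome lengths were used here. Chromosome shares were compared with shares of this span by exact binomial tests (two-sided), with Benjamini-Hochberg adjustment over 6 chromosomes per list. These tests treat peaks as independent, so clustering of peaks can make their p too small. The centre of an autosome was its middle part from 25% to 75% of the span. Because neighbouring peaks are not independent, X and autosomes were also compared over windows of 1 Mb with a permutation test (100000 permutations). Peaks of each list were divided into 4 groups of equal size by strength, and the strongest and weakest groups were compared by Fisher's exact test (two-sided). Strengths on X and autosomes were compared by a permutation test of their mean ranks (100000 permutations). Both permutation tests treat windows or peaks of different chromosomes as interchangeable, so their p does not measure the spread between chromosomes. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. No test against input was possible because the input libraries have no values of their own, and each replicate has 1 list, which allows no test between replicates.

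The comparisons of peak lists by overlap, strength and chromosome, the rule for named items and the stricter, larger-overlap and single-list alternatives were fixed before the data were examined. The tests of single autosomes and of the X centre, the windows of 1 Mb, strength against chromosome, neighbouring peaks, peaks without a partner, overlap of the strongest peaks and the other random placements were added after seeing the peak lists. The rule named genes at the 20 strongest combined peaks present in both replicate lists, and these peaks are given here by position. 5 planned results needed gene positions or sequence of the WS220 build, namely the promoter share, the genes with a promoter peak, tests of 17 gene lists, the E2F motif and the location of strong peaks relative to promoters. The gene table at hand was of the WBcel235 assembly, positions were not carried between builds, and these results were not analysed here. For the same reason no peak was assigned to a gene, exon or intron, and X's share of genes was not used as a reference. Alternatives covered a stricter peak set, a larger overlap, each replicate list alone and other random placements.

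The overlap and chromosome tests were checked on simulated lists. Of 2987 simulated peaks, 60.3% were made to be shared and 62.1% were found to overlap, chance overlaps included. Of 40 pairs of unrelated lists, 2.5% reached a p under 0.05. An X density set at 0.6 of that of the autosomes made 11.4% of peaks lie on X, and the mean over 50 simulated lists was 11.5%. Of 200 lists with even density, 6.0% reached a p under 0.05. Simulated peaks were placed independently of each other, whereas the real peaks cluster. These checks therefore do not show that the chromosome tests keep this error rate on the real lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.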

Results

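EFL-1 binding was mapped in L1 larvae at 26 degrees C from 2 ChIP replicates. Peaks are called EFL-1 sites below, although the labels disagree on the antibody and no control precipitation was among the 4 samples. EFL-1 is the worm counterpart of mammalian E2F factors and acts with the DP protein DPL-1 and the retinoblastoma protein LIN-35 in control of the cell cycle and of germline genes. The replicate 1 list held 3126 peaks and the replicate 2 list 4540, or 3833 ± 1000 (SD, n = 2). The combined list held 5334 peaks, 1.17 times as many as replicate 2. Peaks were narrow in every list. The median width was 441 bp in replicate 1, 427 bp in replicate 2 and 441.5 bp in the combined list, where the middle 50% of peaks ranged from 346 to 613 bp. The combined peaks covered 2.95 Mb, or 2.95% of the chromosome span. Median peak strength (−log10 q) was 11.6 in replicate 1, 12.7 in replicate 2 and 13.2 in the combined list. Wider peaks were stronger, with a Spearman's rho of 0.58 across combined peaks, which are not independent replicates. Whether this is a property of the q-value or of binding was not tested. Sequencing depth was unknown for every library, so the larger list of replicate 2 could not be separated from a difference in depth.

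The first comparison asked whether the replicates marked the same sites. Nearly every replicate 1 peak was found again. Of the 3126 peaks, 3034 overlapped a replicate 2 peak, which is 97.1% (95% interval 96.4 to 97.6). Random placement gave 5.09% on average and 6.43% at most over 1000 placements (permutation test, one-sided p = 0.001, the smallest possible). In the other direction, 3023 of 4540 replicate 2 peaks, or 66.6% (65.2 to 67.96), overlapped replicate 1, against 3.53% by random placement (permutation p = 0.001, one-sided). The peaks without a partner were weak. The 92 replicate 1 peaks without a partner had a median strength of 2.47, against 12.3 for the 3034 with one, and the 1517 unmatched replicate 2 peaks had a median of 3.85, against 27.4. None of the unmatched peaks lay among the strongest 25% of its list, and the strongest of them reached a strength of 15.1 in replicate 1 and 20.4 in replicate 2.

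Strength ranked the shared sites alike in both replicates. Over 3009 pairs, Spearman's rho was 0.93 (bootstrap interval 0.93 to 0.94) and Pearson's r was 0.95, both across peaks rather than across samples. The values themselves differed. Replicate 2 was stronger at 2845 of 3009 pairs, or 94.5%, and the median ratio of replicate 2 to replicate 1 was 1.86. The strongest peaks were only partly the same. Of the 100 strongest peaks of replicate 1, 65 overlapped 1 of the 100 strongest of replicate 2, a share of 65% (54.8 to 74.3). The share was 87% (83.7 to 89.8) for the strongest 500 and 90.4% (88.4 to 92.2) for the strongest 1000.

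**Figure D1:**
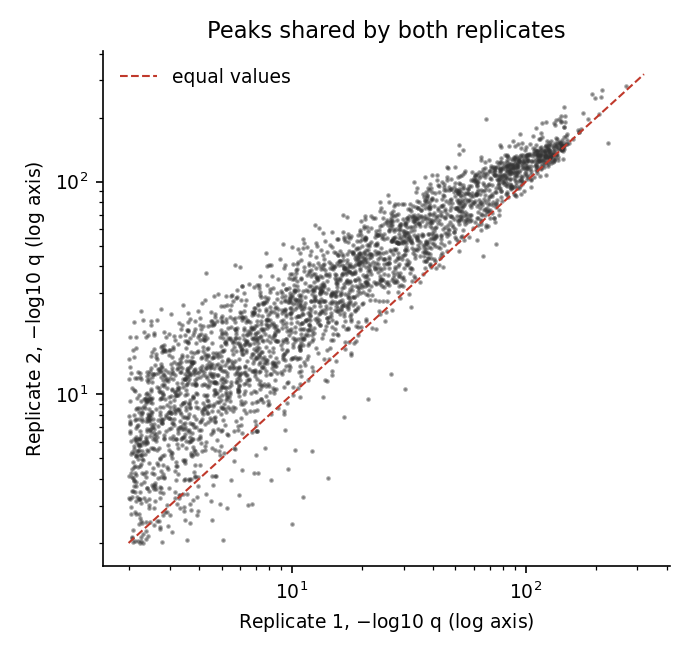
Strength of each of 3009 shared peaks in replicate 1 (x axis, −log10 q) and replicate 2 (y axis, −log10 q), both on log axes; each point is 1 pair of overlapping peaks and the dashed line marks equal values. Points rise together (rho 0.93) and 94.5% of them lie above the line.

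The combined list brought in peaks that the replicate lists lacked. Of its 5334 peaks, 2990 (56.1%, 54.7 to 57.4) overlapped a peak in both replicate lists, 1484 (27.8%) overlapped replicate 2 only, 78 (1.46%) overlapped replicate 1 only, and 782 (14.7%) overlapped neither. Median strength in the combined list fell from 37.9 for the peaks in both lists to 5.52 for those of replicate 2 only, 4.37 for those of replicate 1 only and 2.63 for those in neither. Median width went from 509 bp for peaks in both lists to 313.5 bp for peaks in neither. Among the stronger 50% of combined peaks, 96.2% were in both replicate lists.

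The 20 strongest combined peaks present in both replicates lay on all 5 autosomes, with 4 on chromosome I, 2 on II, 3 on III, 6 on IV and 5 on V. None lay on X. Their strengths ran from 205 to 288 in the combined list, from 85.9 to 269 in replicate 1 and from 111 to 282 in replicate 2. They were 600 to 4328 bp wide, with a median of 1296.5 bp. The strongest combined peak was at chromosome III 13462353 to 13466673 (WS220), 4321 bp wide, with a combined strength of 288. It ranked 2 in replicate 1 and 51 in replicate 2, with strengths of 224 and 152. The next was at chromosome IV 3384344 to 3385872, ranked 3 and 2 in the replicates, with a combined strength of 286. The peak at chromosome V 10031190 to 10032184 had a combined strength of 285 and ranked 6 and 5. The peak at chromosome II 14251031 to 14252291 ranked 1 in both replicates, with strengths of 269 and 282, and had a combined strength of 263. The peak at chromosome I 12531906 to 12532771 ranked 4 in both replicates, with a combined strength of 241. Other members ranked lower in the single replicates. The peak at chromosome IV 10933014 to 10937341, 4328 bp wide, had a combined strength of 207 but ranked 320 in replicate 1 and 338 in replicate 2. The narrowest of the 20 was a 600 bp peak at chromosome V 14054940 to 14055539, which ranked 8 and 13.

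The next comparison asked how EFL-1 sites were spread over the chromosomes. Chromosome III was the most densely bound and X the least. The combined list had 75.4 peaks per Mb on III, 67.9 on I, 58.4 on IV, 55.6 on II, 40.9 on V and 31.5 on X. The replicate lists had the same chromosomes at both ends, with 56.9 ± 12.7 peaks per Mb on III and 20.9 ± 7.1 on X (mean ± SD, n = 2). Because the lists differ in length, shares of each list were compared. Chromosome III held 19.5% of combined peaks on 13.8% of the span, and I held 19.05% on 14.97% (exact binomial test, adjusted p = 5.84e-30 and 1.03e-15). IV held 19.1% on 17.5% (adjusted p = 0.00169 in the same exact test). Since that test treats clustered peaks as independent, this modest difference is uncertain. V held 16.03% on 20.9% (exact test, adjusted p = 4.24e-19). The share of II, 15.9% on 15.3% of the span, was not detectably different (exact test, adjusted p = 0.20). It was above its share of the span in both replicate lists too, by ratios of 1.08 and 1.07 (exact test, adjusted p = 0.0621 and 0.0576).

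X held 556 of 5334 combined peaks, or 10.4% (9.62 to 11.3), on 17.6% of the span, a ratio of 0.59 (exact binomial test, adjusted p = 2.46e-48). The replicates gave 8.96% and 10.0%, a mean of 9.50% ± 0.77 (SD, n = 2), so the gap to 17.6% was far larger than the spread between replicates. Over windows of 1 Mb, the 79 autosomal windows held 58.3 ± 19.2 combined peaks and the 17 X windows 31.5 ± 7.0 (SD over windows; permutation test, two-sided p = 1e-05, the smallest possible). X windows held 19 to 45 peaks and autosomal windows 17 to 100. All X windows come from 1 chromosome, and the autosomes themselves differed, from 40.9 peaks per Mb on V to 75.4 on III. The window test does not measure this spread between chromosomes. Since peaks cluster, the shares were also taken with 1 peak per run of peaks less than 10 kb apart, which left X at 14.1% (exact binomial p = 1.45e-06).

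**Figure D2:**
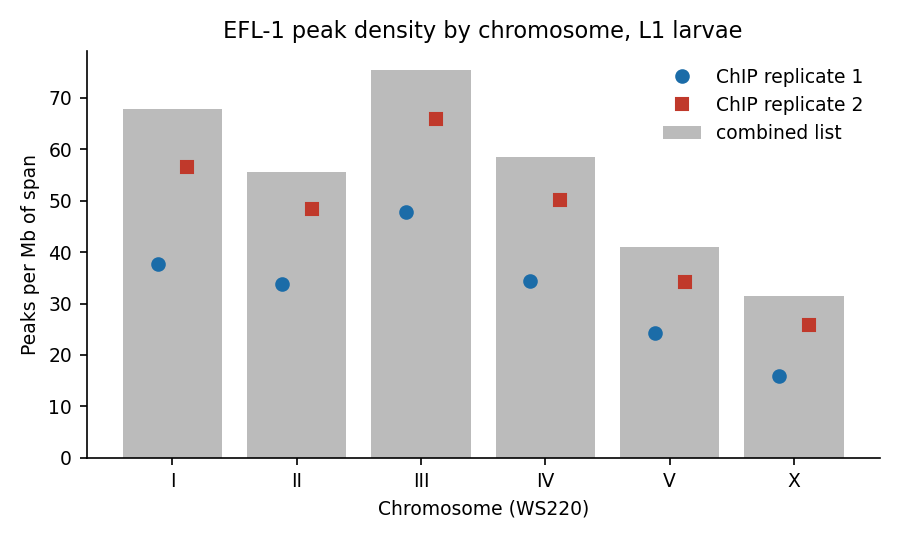
Peaks per Mb of chromosome span (y axis) on each chromosome (x axis); bars show the combined list, circles ChIP replicate 1 and squares ChIP replicate 2. Chromosome III is highest, at 75.4 peaks per Mb in the combined list, and X lowest, at 31.5, with the same extremes in both replicates.

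The shortfall on X grew with peak strength. Only 3.90% (2.92 to 5.08) of the strongest 25% of combined peaks lay on X, that is 52 of 1334, against 15.3% (13.4 to 17.4) of the weakest 25%, 204 of 1333. The odds ratio was 0.22 (Fisher's exact test, p = 9.12e-25). The same contrast was 3.32% against 15.4% in replicate 1 (Fisher's exact p = 3.16e-17) and 4.32% against 16.7% in replicate 2 (Fisher's exact p = 6.62e-23). In the weakest 25%, the X share of the combined list was below its 17.6% of the span (exact binomial test, p = 0.0258), and a difference was not detected in the replicate lists (exact binomial p = 0.10 in replicate 1 and 0.46 in replicate 2). Median strength was 6.62 on X and 14.5 on autosomes in the combined list, 5.01 and 12.6 in replicate 1, and 6.60 and 13.6 in replicate 2 (permutation test of ranks, two-sided p = 1e-05 in each list, the smallest possible). Autosomal medians ran from 11.5 on V to 16.4 on III in the combined list, from 9.83 on IV to 15.3 on I in replicate 1 and from 11.5 on IV to 16.99 on I in replicate 2. Strong X sites did exist. The strongest was at X 8035819 to 8037011, with a combined strength of 173 and rank 39 among all combined peaks, and the next at X 16929326 to 16931978, with a strength of 160 and rank 63. The third, at X 14525302 to 14526591, had a strength of 138 and rank 146.

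**Figure D3:**
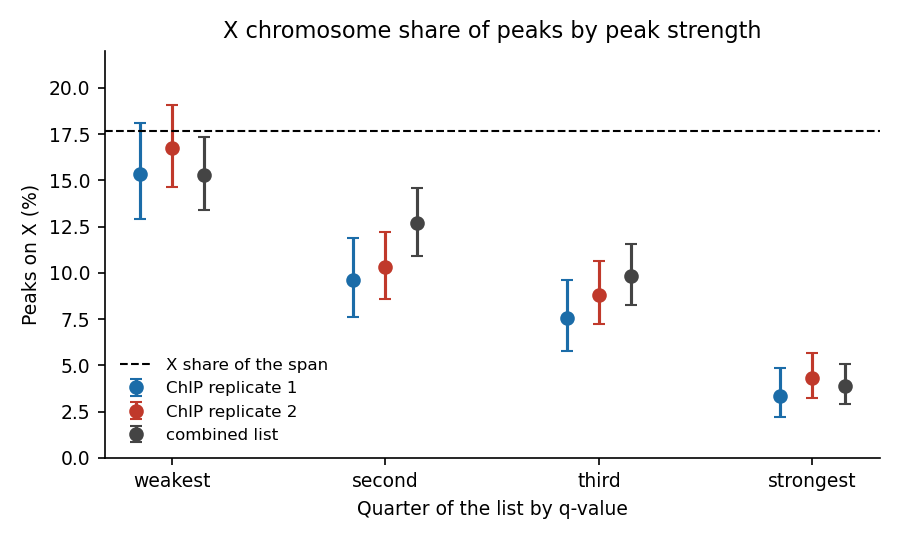
Share of peaks on X (y axis, percent) in 4 groups of equal size by q-value, from weakest to strongest (x axis), for each list; points are shares, bars exact 95% intervals and the dashed line X's share of the span, 17.6%. The combined list falls from 15.3% in the weakest group to 3.90% in the strongest, and both replicates fall likewise.

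Over the autosomes together, sites favoured the chromosome centres, which are known to be gene-rich and poor in recombination. The middle 50% of the autosomal span held 2750 of 4778 peaks, or 57.6% (56.1 to 59.0; exact binomial test, p = 1.46e-25), and 57.6% ± 0.6 over the replicates (SD, n = 2). With 1 peak per run of peaks less than 10 kb apart, the centre share was 54.9% (exact binomial p = 4.14e-06). The excess was largest on V, at 64.4% (61.1 to 67.7), and III, at 59.7% (56.7 to 62.7), with adjusted p of 1.45e-16 and 1.17e-09 in the exact binomial test. It was 56.4% on I, 54.1% on II and 53.6% on IV, where the exact test gave adjusted p of 0.000101, 0.0266 and 0.0290. The exact test treats clustered peaks as independent, so the modest departures on II, IV and X are uncertain. On I, III and V the centre was denser than either end of the chromosome. On II and IV it was denser than 1 end alone. Chromosome II had 39.8 peaks per Mb in the first 25% of its span, 60.1 in the centre and 62.1 in the last 25%, and IV had 67.1, 62.6 and 41.4. X did not share the excess, with 45.3% (41.1 to 49.6) of its peaks in the centre (exact test, adjusted p = 0.0305). It had 30.2 peaks per Mb in the first 25% of its span, 28.6 in the centre and 38.8 in the last 25%. The low centre share of X thus came mostly from 1 denser end. Unlike the X share, the centre share did not detectably differ with strength. It was 57.4% in the strongest 25% of combined peaks and 56.3% in the weakest (Fisher's exact test, p = 0.62).

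**Figure D4:**
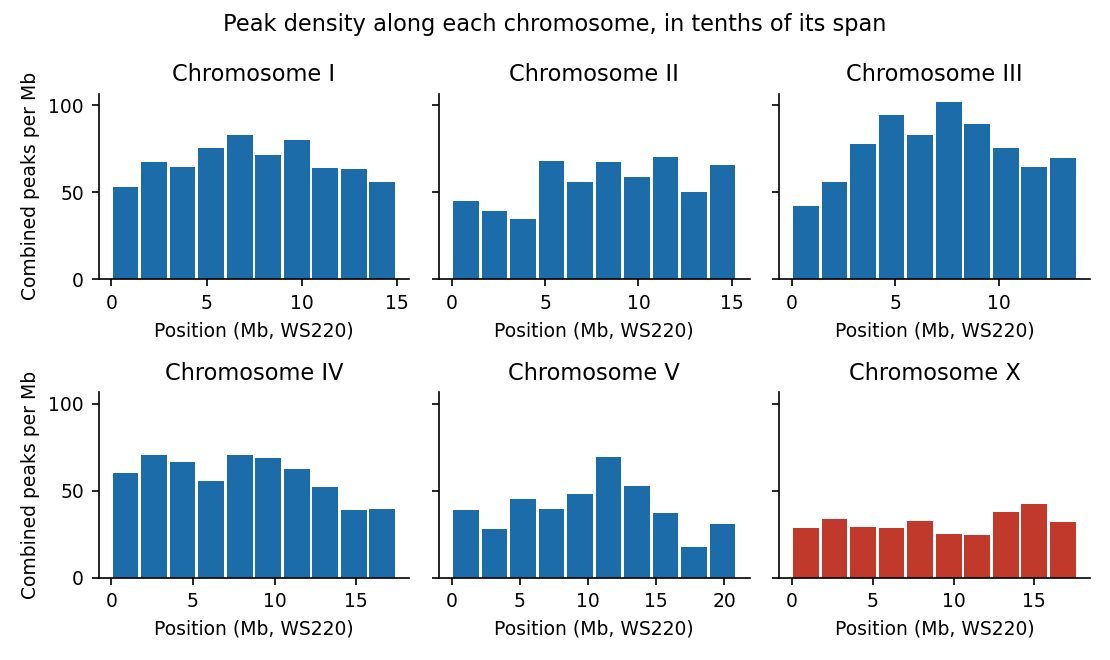
Combined peaks per Mb (y axis) in 10 equal parts of each chromosome's span (x axis, position in Mb on WS220). Chromosomes I, III and V are denser in the middle, IV is sparse at its end and II at its start, and X has 45.3% of its peaks in the centre.

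Peaks also lay close together more often than random placement gives. A neighbour less than 1 kb away was present for 1076 of 5334 combined peaks, or 20.2% (19.1 to 21.3), against 16.1% on average and 18.04% at most over 1000 placements (permutation test, one-sided p = 0.001, the smallest possible). Placement was even along each chromosome, so denser chromosome parts enter this excess. Neighbouring peaks need not be separate sites. The replicate 1 peak at chromosome V 6220727 to 6230085 was called in replicate 2 as separate peaks, at 6220755 to 6221873 and 6222362 to 6229976. How far such divided regions add to the excess was not tested. The median gap between neighbouring peaks was 9128 bp. The densest windows of 100 kb, at chromosome III 7100001 to 7200000 and chromosome IV 4000001 to 4100000, held 18 peaks each. The 5 longest stretches without a combined peak were all on V, the longest being 341051 bp, from 16966988 to 17308038.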

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

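The added placements, the thinning of runs of peaks, covered bases, the split by strength with its single-list versions and the neighbour gaps were chosen after seeing the peak lists. Of 30 alternative values over 10 results, 28 kept their direction and side of the threshold or, without a test, stayed within the replicate SD or the 95% interval, and 2 without a test moved by more. The X share of the weakest 25% entered this count for the whole combined list only. It was not detectably below 17.6% in replicate 1, replicate 2 or the combined peaks in both lists (exact binomial p = 0.10, 0.46 and 0.36). The share of combined peaks found in both replicate lists was 56.1% for all peaks and 96.2% for the stronger 50%, which by construction removes the weak peaks. The X share was 10.4% of peaks and 12.2% of covered bases, which by construction counts wide peaks for more (median width 474.5 bp on X and 436.5 bp on autosomes). Without either replicate, the X share was 8.96% to 10.0% and the centre share of autosomal peaks 57.1% to 58.0%. The X share was 6.86% among the stronger 50% of combined peaks, 8.60% among peaks in both replicate lists and 14.1% with 1 peak per run, which thins dense chromosomes most, and each of these stayed below 17.6%. Overlap of replicate 1 with replicate 2 exceeded chance by 92.0 percentage points with random placement and by 91.1 when peaks were shifted by 5 to 20 kb. Read numbers are unknown, so what depth limits in each list was not assessed. Without either replicate, the X share of the strongest 25% minus that of the weakest was -12.42 to -12.04 percentage points. Promoter, gene list, motif and score-by-location results, with their alternatives, were planned and not run, since they need positions on WS220. No paired analysis was possible because the input libraries have no values of their own, so ChIP and input could not be compared by replicate number.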

Other observations

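The widths on X, the widest peaks, the combined strengths, the strength of the absent region and the distance of wide peaks from the line were tested or compared only after seeing the data. For the low density on X, the peak counts per chromosome, though not their split by strength, had been seen when its tests were set. Predictions and bounds called set beforehand below were set before the value of their own test was seen, not before the peak lists were at hand. X peaks were wider than autosomal peaks of like strength. In the 4 groups of combined peaks by strength, from weakest to strongest, median widths were 402.5, 446, 536 and 823 bp on X and 311, 378, 449.5 and 606 bp on autosomes. Within these groups, X peaks stood 14.9 percentile points higher in width on average (permutation within groups, two-sided p = 0.0001, the smallest possible with 10000 permutations). This permutation treats peaks of different chromosomes as interchangeable, so its p does not measure the spread between chromosomes. Over all combined peaks, median widths ran from 419 bp on III to 463 bp on V among autosomes, against 474.5 bp on X. Of the 25 combined peaks at least 3 kb wide, 6 were on X, or 24%, against 10.4% of narrower peaks (Fisher's exact test, two-sided p = 0.0395, odds ratio 2.73). All 25 were found in both replicate lists. The widest were 8712 bp at chromosome II 10541867 to 10550578, 7097 bp at chromosome I 7079089 to 7086185 and 6320 bp at chromosome II 11974134 to 11980453, with combined strengths of 161, 146 and 171.

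At the 2990 combined peaks found in both replicate lists, the combined strength was a median 1.32 times that of replicate 2 and 0.93 times the sum of both replicates, and it exceeded both replicates at 2660 peaks. These medians do not describe strong peaks. The ratio to the sum was 1.13 at peaks with a replicate 2 strength under 10, 0.55 from 100 to 150 and 0.56 from 150 to 300, and the combined strength exceeded both replicates at 572 of 575, 178 of 362 and 39 of 58 of them. Grouping by replicate 2 strength can by itself raise ratios in the low groups and lower them in the high ones. How the list was combined is not given in the sources used here.

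A strong region seen in both replicates was absent from the combined list. At chromosome V 6220727 to 6230085, replicate 1 had its widest peak, 9359 bp, with a strength of 144, and replicate 2 had its widest, 7615 bp, with a strength of 146, while no combined peak lay between 6214229 and 6230725. The combined list lacked 12 replicate 1 and 29 replicate 2 peaks, with median strengths of 2.18 and 2.33, and 2 of these, both in this region, were in the strongest 10% of their own list. The bound set beforehand, fewer than 5 such peaks, was met. Among so few absent peaks it would often be met whatever their strength, so it decides nothing. The low median strengths leave weakness near the q threshold as an explanation for most absent peaks. The bound also did not ask how strong the region was. Strengths of 144 and 146 in the replicates argue against weakness for the region itself. A q-value too small to be held as a number stays open. A straight line through 2990 peaks present in all lists predicts a combined strength of 151 there, below the bound set beforehand against this explanation and the 308 at which double-precision numbers end. That bound was wrong for wide strong peaks. The 7 that were at least 3 kb wide and above 50 in both replicates lay a median of 79.8 (32.8 to 132) above the line. The 225 peaks above 100 in both replicates, whatever their width, had a median distance of -5.77 from it, that is below the line. For loss in the lift-over, the bound set beforehand came out against it, since 100% of these 2 peaks were kept in the other replicate list. That bound was ill chosen and the question is left open, because both peaks are 1 region, and a combined peak with other edges could have been treated differently. A filter on wide peaks was not tested.

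The low density on X did not come from a single dense 1 Mb window on each autosome, and technical explanations stay open. If 1 dense cluster per autosome made the difference, it would vanish without the densest 1 Mb window of each chromosome. The sparsest autosome then still exceeded X by 8.58 peaks per Mb. No autosomal window held more than 100 peaks, while V, the sparsest autosome, held 855 and X held 556. That outcome was therefore close to fixed by peak counts that had been seen, and it bears on single windows only. Loss of weak X peaks at the q threshold stays open. X held 3.90% of the strongest 25%, well under 17.6%, which met the bound set beforehand against this explanation. That bound was wrong, because a lower signal over the whole of X would take strong peaks as well as weak ones, and median strength was 6.62 on X against 14.5 on autosomes. Gene density on X, mappability and input coverage were not tested, and no biological explanation was tested because the design has no group that bears on it.

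The 782 combined peaks found in neither replicate list were weak, as predicted if weak sites were gained near the threshold. Their median strength was 2.63, below the lower quartile of 4.66 for the combined list, and 95.9% of them lay in that lowest 25%. Peaks that missed the threshold in both replicates are likely to be weak in a combined list whatever their cause. The values therefore do not show where these peaks came from, nor that they are bound sites.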
